A study of Ctenopharyngodon idella with 2 samples.

How the data were processed

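Spleen RNA of grass carp (Ctenopharyngodon idella), a farmed freshwater cyprinid fish, was sequenced in 2 libraries, 1 from normal temperature and 1 from high temperature treatment. The temperatures, the length of exposure and the number of fish behind each library are not given in the sources used here. Total RNA was extracted with Trizol and made into Illumina libraries, per the labels' protocols. CASAVA 1.7, Illumina's software for base calls and sample sorting, and HISAT, a splice-aware read aligner, are named in the submitters' processing notes. The HISAT version, the counting tool, the genome build, the gene annotation and any use of strand are not given in the sources used here.

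The authors deposited a table of whole-number read counts per gene and a table of FPKM (fragments scaled by gene length and by the library total), each with 27929 gene IDs and 1 column per library. The deposited counts are not normalized and sum to 16658918 in the normal temperature library and 20936717 in the high temperature library. The authors' FPKM values were checked against the counts. For all 4802 IDs with at least 1000 counts over both libraries, each FPKM value equalled the count divided by 1 whole-number gene length and by the library total, within 0.0001. The FPKM table is therefore no second measurement, and it was used only to recover gene lengths and as an alternative scale. Lengths were recovered to within 0.2 bases for 22174 IDs, and 76.2% of these were divisible by 3.

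Of the IDs, 27852 have the form of a sequence name followed by 2 position fields. For 22123 of these with a precise length, the length equalled the span between the fields in 1963 and exceeded it in 17, and the fields are read here as start and end on that sequence. The other 77 IDs carry no position. The files do not pair the IDs with gene names, and none of the 27929 IDs matched the reference gene table of this species in its gene IDs, symbols or accessions. Gene lists and cell type markers had been fixed before the data were examined, as had the counting rule, the naming rule and most alternatives. Without names the lists, the markers and the planned comparison of list medians with 10000 random lists could not be applied. Gene and cell type names are thus not reported.

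With 1 library per group there is no residual spread to estimate, and edgeR's quasi-likelihood test was not fitted. Counts were scaled between the libraries with edgeR 4.0.16 TMM factors (R 4.3.3), and genes with at least 20 counts over both libraries were compared. For each gene, the exact Clopper-Pearson 95% interval of the high temperature share of its counts was turned into an interval of the scaled ratio, high over normal temperature. A gene was counted as higher when this interval lay wholly above 2 and as lower when it lay wholly below 0.5. These intervals cover counting error only, with each read taken as an independent draw, since the difference between fish was not measured. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. The intervals compare the 2 libraries, not the 2 conditions, and no p-value is given. Log2 ratios carry a prior count of 0.5. A count of 0 allows up to 3 counts, or 0.18 and 0.143 CPM (counts scaled by the library total) in the normal and high temperature libraries. By the naming rule for IDs without names, the 2 higher IDs with the highest lower bounds and the 2 lower IDs with the lowest upper bounds are named.

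The counting rule was tested on simulated data drawn for the 19006 measured genes of this comparison, with counting noise only and no variation between libraries. It recovered 83.8% of 68 genes altered 3-fold, 93.9% of 66 altered 4-fold and 97% of 66 altered 8-fold, and counted 0 of 18806 unaltered genes. With counting noise alone that 0 was nearly fixed in advance, so it is no error rate for real libraries. Unaltered libraries were also simulated with assumed biological coefficients of variation of 0.1, 0.2 and 0.4. Alternatives were library totals, DESeq2 1.42.0 size factors, upper quartile scaling, totals without the 10 most abundant genes, other count minimums, bounds and intervals, and the authors' FPKM. After the data were seen, thinning of the high temperature counts to the normal temperature total, grouping by abundance and length, and runs of neighbouring genes were added. Runs were compared with 1000 shuffles of the genes' positions. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps.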

Results

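Gene expression in the spleen of grass carp, an organ of blood cell turnover and immune defence in fish, was compared between a normal and a high temperature treatment to examine the immune response under heat. Each treatment was represented by 1 RNA sequencing library, so no difference below has a replicate check. The normal temperature library held 16658918 gene counts and the high temperature library 20936717. Counts above 0 were found for 24507 gene IDs at normal and 26249 at high temperature, of 27929 listed. When the high temperature counts were thinned to the normal temperature total, 25756 IDs still had a count. Across the 19006 genes with at least 20 counts over both libraries, the counts of the 2 libraries were correlated with a Spearman's rho of 0.936, a value across genes, which are not independent replicates.

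The most abundant transcripts were largely shared. The same gene ranked first in both libraries and took 3.28% of all counts at normal and 2.55% at high temperature. The 10 most abundant genes took 17.2% and 15.6%, respectively, and the 100 most abundant took 42.4% and 39.1%. The top 100 of both libraries had 80 genes in common. Among the 120 genes in the top 100 of either library, 21 were lower and 8 were higher at high temperature by more than 2-fold beyond counting error (18 and 9 with library totals).

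Of the 19006 measured genes, 929 (4.89%) were higher and 835 (4.39%) were lower in the high temperature library, with counting intervals wholly beyond 2-fold. The lower genes were the more abundant, with a median of 26 scaled CPM against 5.63 among the higher genes. Their median count was 632 at normal and 262 at high temperature, and together they took 16.2% of all normal temperature counts and 4.79% of all high temperature counts. The higher genes had a median count of 31 at normal and 203 at high temperature, and their joint share was 2.31% against 7.13%. The median ratio among the lower genes was 0.307. Beyond 4-fold by the same rule were 198 higher and 158 lower genes, and beyond 8-fold 51 and 35. Among genes with at least 20 counts over both libraries, 34 had no count at normal temperature and at most 101 at high temperature, whereas 3 had no count at high temperature and at most 35 at normal temperature. That minimum acts on unscaled counts, so genes absent at normal temperature pass it at a lower scaled level, and depth favours the 34. The share of higher genes among those beyond 2-fold was 52.7% with TMM scaling and 65.7% with library totals, which placed the ratios 0.16 higher on the log2 scale. The balance turned to 45.9% with a minimum of 100 counts (642 higher and 757 lower) and to 47.0% with a stricter confidence level (551 and 621). Unaltered libraries simulated with an assumed biological coefficient of variation of 0.4 gave 2159 genes beyond 2-fold, 147 beyond 4-fold and 4 beyond 8-fold, so the number beyond 2-fold did not exceed that simulation, while the numbers beyond 4-fold and 8-fold did.

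**Figure D1:**
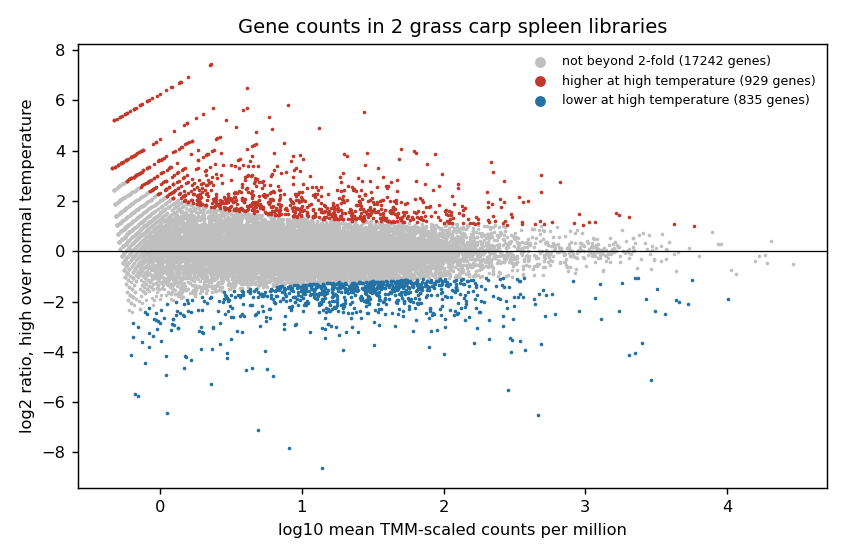
Log2 ratio of each of 19006 measured genes (high over normal temperature, TMM-scaled counts) against the log10 of its mean scaled CPM. Red points are the 929 genes higher and blue points the 835 genes lower by more than 2-fold beyond counting error, with 1 library per treatment. The red points crowd toward low abundance and the blue points toward middle and high abundance.

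By the bound of the counting interval nearest to no difference, 4 genes ranked first, 2 in each direction, and the files list them without names. Sparser genes had ratios more extreme than some of these, with wider intervals. CI01000174_00359594_00362813, on sequence CI01000174 from 359594 to 362813 by its ID and 1360 bases long as counted, had 18 counts at normal and 1189 at high temperature. Its scaled ratio was 46.9 (95% counting interval 29.6 to 79.5), and its FPKM was 0.795 at normal and 41.8 at high temperature. CI01000146_00670994_00674390, from 670994 to 674390 and 750 bases long, had 4 counts at normal and 347 at high temperature, a ratio of 61.6 (23.9 to 227.5). Among the lower genes, CI01000238_00182005_00186316, from 182005 to 186316 and 2109 bases long, had 14489 counts at normal and 221 at high temperature. It was 92.3-fold lower at high temperature (80.8 to 105.9), and its FPKM was 412 and 5.01 in turn. CI01098000_00000053_00000454, a gene of 402 bases whose length equals its span from 53 to 454, had 438 counts at normal and 1 at high temperature, a ratio of 0.0016 (4.1e-05 to 0.0091). On the log2(FPKM + 1) scale, which understates the change of low values, the log2 ratio was 4.575 for CI01000174_00359594_00362813 against 5.52 from counts, 4.13 against 5.81 for CI01000146_00670994_00674390, -5.89 against -8.60 for CI01098000_00000053_00000454 and -6.105 against -6.52 for CI01000238_00182005_00186316. The build behind these positions and the exon structure of the genes are not given in the sources used here.

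Several differences came in blocks of neighbouring genes. Runs of at least 4 consecutive measured genes that all differed in the same direction numbered 8 for higher and 4 for lower genes. In 1000 shuffles of the genes' positions, at most 2 such runs of either direction were found. The shuffles also break any clustering of genes alike in abundance or length. Whether genes of 1 run are near-identical copies, and how the authors' counting divided reads between copies, is not given in the sources used here, so the ratios of single members are uncertain.

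The most abundant block was a stretch of 78.1 kb on CI01000113, from 254945 to 333023, with 9 measured genes. Of these, 8 were lower at high temperature. They are 417 to 444 bases long and together took 3.6% of all counts at normal temperature and 0.937% at high temperature. Their summed counts were 599175 and 196201, which is 4.3-fold lower at high temperature (95% counting interval 4.28 to 4.32). The sum blends genes of unlike ratio, so its narrow interval describes the sum and no common ratio. The ratios of single genes ran from 0.0605, in the gene from 285871 to 286497, to 0.31, in the gene from 256900 to 257501. The most abundant gene of the block, from 324040 to 324756, had 252481 counts at normal and 95174 at high temperature. The remaining gene of the stretch was sparse, with 26 and 65 counts, and its ratio of 1.78 (1.11 to 2.92) did not exceed 2-fold beyond counting error.

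**Figure D2:**
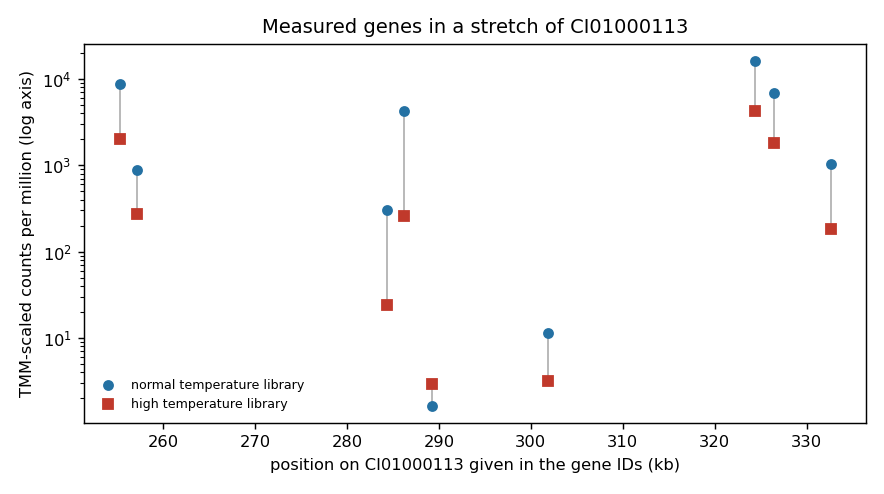
TMM-scaled CPM (log axis) of the 9 measured genes between 254945 and 333023 on CI01000113, plotted at the position given in their IDs (kb). Circles are the normal and squares the high temperature library, joined by a line for each gene. In 8 of the 9 genes the high temperature library lies lower.

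At normal temperature, the next most abundant run lay on CI01000238, from 182005 to 246057, and held the gene with 14489 counts described above. Its 4 genes summed to 24994 counts at normal and 1423 at high temperature, which is 24.7-fold lower (23.4 to 26.1). The ratios of its single genes ran from 0.0028 to 0.0844, with a median of 0.0077. The lowest ratios came from its sparser genes, with very few high temperature counts, and the median rests partly on these. The summed ratio and its interval blend genes of unlike ratio, since the gene with 14489 counts was itself 92.3-fold lower. The run of 4 lower genes on CI01000004, from 8976512 to 9004879, had 1992 and 866 counts, a ratio of 0.309 (0.285 to 0.335). The other runs of lower genes were both part of the CI01000113 stretch. In the opposite direction, 5 consecutive genes on CI01000006, from 5617900 to 5888691, had 66 counts at normal and 1354 at high temperature, a ratio of 14.6 (11.4 to 19). On CI01000020, from 1585338 to 1665929, 4 genes had 1690 and 19706 counts, a ratio of 8.29 (7.88 to 8.71). On CI01000319, from 4724377 to 4760920, 4 genes had 410 and 5083 counts, a ratio of 8.81 (7.96 to 9.77). These summed ratios of higher genes also blend unlike genes. Single ratios ran from 8.77 to 30.8 on CI01000006, 7.3 to 31.1 on CI01000020 and 4.86 to 25.3 on CI01000319. The other 5 runs of higher genes had summed ratios from 2.79 on CI01000340 to 4.61 on CI01000146.

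Sparse genes were shifted upward as a group at high temperature. In the lowest abundance quintile, below 2.24 scaled CPM, the median log2 ratio was 0.36 with TMM scaling and 0.52 with library totals. With TMM scaling, 280 of 3802 genes were higher and 60 lower, against 355 and 53 with library totals. In the highest quintile, above 34.1 scaled CPM, the median was -0.05 with TMM scaling and 0.11 with library totals. There, 186 of 3801 genes were higher and 349 lower with TMM scaling, against 250 and 264 with library totals. The lowest quintile lay 0.46 above the middle quintile, whose own median was -0.10 with TMM scaling and 0.06 with library totals. A minimum of 100 counts removes every gene of this lowest quintile. With quintiles drawn anew among the remaining, more abundant genes, the lowest had a median of 0.085, which does not describe the sparse genes above.

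Long genes were likewise placed above short genes. The median log2 ratio was 0.09 in the longest quintile, of 2334 bases or more, and -0.06 in the shortest, up to 598 bases, with TMM scaling, and 0.25 and 0.10 with library totals. Among genes with at least 100 counts, the longest quintile had a median of 0.042. Among the longest genes 235 were higher and 107 lower (314 and 75 with library totals), and among the shortest 143 were higher and 192 lower (176 and 141 with library totals). Within the lowest abundance quintile the median was 0.69 for the longest and 0.16 for the shortest genes, whereas within the highest abundance quintile these medians were -0.01 and -0.10 with TMM scaling, which places all ratios 0.16 below those from library totals.

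**Figure D3:**
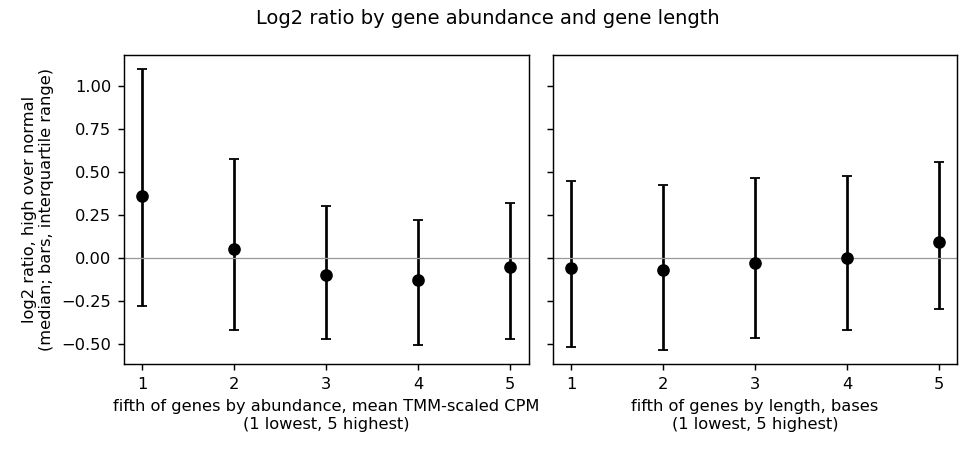
Median log2 ratio (high over normal temperature, TMM-scaled) in quintiles of the 19006 measured genes, by mean abundance (left) and by gene length (right), with bars for the interquartile range across genes. The median is 0.36 in the sparsest and -0.05 in the most abundant quintile, and 0.09 in the longest and -0.06 in the shortest. With library totals these medians are 0.52, 0.11, 0.25 and 0.10 in the same order.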

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

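Between 5 scalings, the counts of higher and lower genes stayed within 1.5 times 929 and 835. The stricter 4-fold bound left 198 higher and 158 lower genes, a stricter confidence level left 551 higher and 621 lower genes, and the point ratio without an interval gave 2237 higher and 1652 lower genes. On the authors' FPKM, without an interval or a count minimum, 1518 genes were higher and 852 lower with a pseudocount of 1, where a minimum FPKM of 1 can remove no such gene. With a pseudocount of 0.1, the only setting changed, the numbers were 4792 and 1989. Both FPKM settings differ from the main one in scaling, interval, count minimum and pseudocount, and the part of each was not separated. Leaving out the 10 genes with the most counts over both libraries lowered, by construction, the share of the top 10 from 17.2% to 7.81% at normal temperature. At high temperature it fell from 15.6% to 7.66%. The share of the top 100 fell from 42.4% to 32% at normal and from 39.1% to 30.1% at high temperature. The later shares belong partly or wholly to other genes and are taken of the reduced totals. With quintiles drawn anew under each alternative, the median log2 ratio of the sparsest ranged from 0.085, with a minimum of 100 counts, to 0.5, with library totals. The minimum of 100 counts puts other, more abundant genes in that quintile, so its value is not a check on the sparse genes of the main setting. Thinning the high temperature counts to the normal temperature total, an alternative chosen after seeing the data, gave 904 higher and 808 lower genes. With 1 library per treatment no library could be left out. No paired analysis was possible because each treatment has 1 library. The alternatives foreseen for gene list medians were not run, since no ID had a name.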

Other observations

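Adjacent genes had correlated ratios. Over 17487 pairs of adjacent measured genes, Spearman's rho between their log2 ratios was 0.125, against at most 0.0229 in 1000 shuffles of the positions. The shuffles also break any clustering of genes alike in abundance or length, and reads shared between neighbouring copies were not separated. Without the genes of the runs of 4 or more, rho was 0.12 over 17427 pairs, against at most 0.0231. The value was 0.184 for pairs under 5 kb apart, 0.109 for gaps of 5 to 20 kb, 0.0556 for 20 to 100 kb and 0.0279 for wider gaps, where it lay inside the shuffled range of -0.054 to 0.054. Of the 77 IDs without a position, 34 were measured, of which 6 were higher and 3 lower at high temperature.

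The tests on the CI01000113 block were chosen after its values were seen, and the tests on the number of differing genes and on sparse genes were written down before their results. Each concerns a hypothesis found in these same 2 libraries.

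The number of genes beyond 2-fold cannot be told apart from variation between the sampled fish, because each treatment has 1 library. Unaltered libraries simulated with an assumed biological coefficient of variation of 0.4 gave 2159 such genes, and the 2 libraries treated as 1 group had a common coefficient of 0.388, which includes any effect of temperature. At an assumed 0.2 the simulation gave 67 genes. The tail was heavier than in the simulation at 0.4, with 51 higher and 35 lower genes beyond 8-fold against 4, but genes that vary more than the assumed common value would produce such a tail too. An effect of temperature stays open and untested.

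For the upward shift of sparse genes at high temperature, the lowest abundance quintile, after thinning to equal totals, still lay 0.419 above the middle quintile. This argues only against unequal totals acting through the count minimum and sampling noise as the whole cause. Thinning leaves the expected scaled ratio of each gene unchanged, so it cannot decide on other effects of deeper sequencing. An even background large enough for the shift needs 3.51 counts per kilobase. Of 592 genes of at least 2 kb with 1 to 3 normal temperature counts, 18.75% had no thinned high temperature count. Such a background leaves 0.0186%, so an even background of that size is argued against for these genes. Of 2783 genes with 5 to 15 normal temperature counts, 3.99% lay below it, where at most 2.5% were allowed. That limit takes each read as an independent draw, so the small excess does not decide. The same check within the lowest quintile gave 0.75% but was void, because the minimum of 20 counts removes genes with low counts. Within that quintile the median log2 ratio was 0.69 for the longest and 0.16 for the shortest genes. A background per kilobase would give that direction too, so a smaller even background stays open. Uneven background and a different mix of cells or tissue in the dissected spleen stay open as well. So do an effect of temperature and a difference in RNA integrity, which may bear on the trend with length.

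The lower counts of the CI01000113 block were weighed against scaling and read sharing. The highest upper bound of the summed ratio over 5 scalings was 0.262, so the choice among these scalings does not account for it. Their factors, high over normal temperature, lay only between 1.26 and 1.41, so this check could hardly have come out otherwise. Reads shared evenly between all 8 genes would give 1 ratio, but the lower bound of the highest was 4.83 times the upper bound of the lowest. For 3 of the genes, from 301490 to 326875 and 429 to 444 bases long, the ratios of 0.273, 0.268 and 0.263 lay close together. Their normal temperature counts differed up to 1387-fold, which even sharing among them would not give. That figure rests on the gene with 182 counts, whose ratio interval of 0.204 to 0.362 is wide. The genes with ratios of 0.268 and 0.263 had 252481 and 108933 counts, also unequal but far closer. An effect of temperature and uneven sharing of reads stay open, and no biological explanation was tested.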
